A study of Zea mays with 18 samples.

How the data were processed

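The samples were leaf and root small RNA libraries of maize inbred line Q319, 18 in all, with 8 from sufficient phosphate and 10 from low phosphate. Per the series' design text, HiSeq tags of 50 nt were cleaned of low-quality tags and contaminants and annotated, and known miRNAs were counted. The aligner, the miRBase release and the genome build are not given in the sources used here. For the sufficient-phosphate table the authors deposited values read here as a raw count per miRNA and library. All values are whole, single entries reach 3280145, and scatter of low values between replicates is near the counting level, although a suffix in the column names that marks scaled values elsewhere is not explained. For the low-phosphate table the deposited values are a signal, the count divided by the library's total of clean reads and scaled to 1000000 (RPM), per the series' design text. A deposited 0.01 stands for 0 reads (27 cells), and 253 cells are blank where both libraries of a comparison were under 1. For 13 miR399 cells in root on day 1 the value repeats day 0 with no fold, and these were treated as blank. The authors' deposited log2 folds, their p-values and their significance marks compare single libraries, and only the marks were counted, since the test behind them is not given in the sources used here. In the sufficient-phosphate table, headings of the fold columns conflict with those of the value blocks, and the blocks were followed. Likewise 2 root libraries carry day 8 in their titles and day 0 in another label, and the titles were followed.

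The steps of the low values gave the depth of the low-phosphate libraries: 100% of the low values in each library were whole reads within 0.03 reads. Leaf depths were 13500000, 13021000, 15952000, 12885000 and 18079000 clean reads on days 0, 1, 2, 4 and 8, and root depths were 16297000, 21385000, 20489000, 17483000 and 15470000. A floor of 3 reads then equals 0.14 to 0.233 RPM. Sufficient-phosphate totals over listed miRNAs, which count shared reads once per entry, ranged from 8528196 to 14285855. Several members of a family share reads, so values of near-identical members are uncertain and are not independent.

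Entries of a family with identical values in every library were counted once, leaving 197 of 246 entries in 25 families at sufficient phosphate and 156 of 207 at low phosphate. A name listed in 2 places at sufficient phosphate was kept as separate entries. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, robust quasi-likelihood fits, a minimum of 10 counts in at least 2 libraries, and 1 coefficient per group over 8 libraries with 4 residual degrees of freedom. The SE given with edgeR was the absolute log2 change divided by the square root of the F statistic, not a fitted standard error. It is unreliable where the log2 change is near 0. The upper 95% bounds of the age test were built from it. TMM factors were 0.734 to 0.937 in leaf and 1.23 to 1.29 in root. The low-phosphate signal was tested with limma 3.58.1 (trended and robust) on log2(value + 1), blanks set to 0.5, with at least 1 RPM in at least 2 libraries. Such a log2 scale understates changes of rare miRNAs. Trends were fitted on log2(day + 1) within each organ, and leaf against root without day. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05, per contrast. Single-library folds were compared on log2(value + 1) by a rule of at least 2-fold and 10 RPM. Folds against 0 counts use a floor of 3 counts, and counting intervals are exact 95% binomial intervals. Ratios from low counts needed at least 10 counts in the higher organ, a minimum lowered from 20 after the values were seen, so that miR399e and miR399i on day 8 were included.

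Lists of miRNA families, the main tests and the rule for named entries were fixed before the data were examined. The lists were phosphate starvation (miR399, miR827, miR2111), copper and laccase (miR397, miR398, miR408, miR528, miR857), sulfate (miR395), NF-Y (miR169), phase change (miR156, miR157, miR529, miR172), auxin and TAS3 (miR160, miR167, miR390, miR393), growth regulators (miR159, miR164, miR166, miR171, miR319, miR396), silencing machinery (miR162, miR168), star strands, and reproductive phasiRNA triggers (miR2118, miR2275), of which 0 entries were measured. Lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over lists within a contrast. For single-library folds, 10000 random lists were drawn from the 20 nearest entries in mean expression. The list's own members and the phosphate entries were not left out of the draws. Named were all miR399 and miR827 entries past the filter, up to 10 highest and 10 lowest called log2 values per contrast with a mean of at least 10 and replicates that do not overlap, or the 5 lowest p where fewer than 5 passed. Also named were the 5 highest and 5 lowest day 8 folds per organ at low phosphate that went the same way on day 4, the 3 most abundant entries per organ, and up to 3 abundant entries per list. For the low-phosphate trends the minimum of 10 RPM was applied to the highest library.

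Abundant entries by list had these mean levels at sufficient phosphate: miR168b 56001, miR166h 11831, miR408b* 2453, miR167b 2321, miR397b* 1118, miR167h* 638, miR169r 116, miR169c 116 and miR395b* 1.62 CPM. At low phosphate miR168a had 84638, miR166f 11864, miR167j 2206, miR169r 78.8 and miR395e 5.54 RPM.

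Alternatives fixed before the data were examined were median-ratio scaling, scaling to listed reads, other pseudocounts, no filter, a stricter filter (50 counts or 10 RPM), DESeq2 1.42.0 for counts, no trend or robust setting, separate identical entries, a replicate block, fits of the compared groups alone, a linear day scale, day as a factor, other size rules, and leaving out each library. Added after the data were seen were limma on log2 counts, merging of near-identical entries, other values for blanks, edgeR on recovered reads, and tests of age, scaling and capture. The scripts were tested on simulated data. For the leaf stage contrast, 144 entries with 10 changed at each size, 5 of 10 were called at 1.5-fold, 9 at 2-fold and 10 at 4-fold, with 3 false calls. For the leaf trend, 147 entries, 4 of 10 were called at a slope of 0.5 and 10 of 10 at slopes of 1 and 1.5, with 1 false call. In both, 0 were called in an unchanged contrast. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The third deposited table, a selection of the low-phosphate entries with 16 per-sample value columns, was not used here. The 2 phosphate tables were normalised separately, so no test crosses them.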

Results

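Small RNA was sequenced from leaves and roots of seedlings of the maize inbred line Q319, raised in nutrient solution. Plants kept at sufficient phosphate (SP) had 1000 μM KH2PO4, and plants moved to low phosphate (LP) had 5 μM. At SP each organ had 2 libraries on day 0, the 3-leaf stage, and 2 on day 8, the 4-leaf stage. At LP each organ had 1 library on each of days 0, 1, 2, 4 and 8, so no LP time point had a repeat. Day 0 of this series marks the start of the treatment, before any days at low phosphate. Each biological repeat came from 15 to 20 plants, per the series' design text, so spread between SP libraries is spread between pools of plants. The SP counts over all listed miRNAs summed to 12388831 and 14285855 in leaf on day 0 and to 13284761 and 13130158 in leaf on day 8. Root totals were 11136205 and 9505134 on day 0 and 10524030 and 8528196 on day 8. The LP libraries held between 12885000 and 21385000 clean reads, a depth recovered from the steps of their values, and LP levels are given as reads per 1000000 clean reads (RPM). One entry, miR528b, took 21.4 to 27.2% of the SP leaf counts with identical entries counted once, while the largest entry in root, miR168a, took 8.33 to 10.0%. Leaf and root were the main division among the SP libraries, with 93.8% of the variance on the first principal component. Replicates correlated across miRNAs at r of 0.996 or 0.997, and the median absolute log2 difference between them was 0.50 in leaf on day 8 and between 0.18 and 0.21 in the other SP groups.

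The first question was how leaf miRNAs changed with 8 days of growth at sufficient phosphate, the study's growth control. In leaf, 15 of 149 tested entries fell and 0 rose, and 10 of the 15 belonged to miR156, which targets SPL factors. Many miR156 entries are near-identical and share reads, among them miR156a, miR156f and miR156g, so the 10 are not independent. miR156a fell from 72042 ± 1680 to 52322 ± 424 CPM (TMM-normalised counts, SD, n = 2), a log2 change of -0.46 (SE 0.088, edgeR adjusted p = 0.00575). Star strands (the opposite arm of the hairpin) of miR169, a family that targets NF-YA transcription factors, made up 4 of the others. miR169j* fell from 8.03 ± 1.15 to 2.62 ± 0.195 CPM, or 3.04-fold, and miR169c* from 4.65 ± 0.328 to 1.67 ± 0.284 CPM, or 2.75-fold (SD, n = 2). The remaining entry was miR408b*, from the hairpin of a miRNA that targets copper-binding plantacyanins, which fell from 5638 ± 240 to 2843 ± 1014 CPM.

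Among the other named leaf entries, miR156b* had the lowest log2 change, -1.80 (SE 0.46, edgeR adjusted p = 0.0275), from counts of 21 and 17 to counts of 7 and 5. The log2 changes of miR156l*, miR169k* and miR169i* were -1.21, -1.06 and -0.94, with edgeR adjusted p of 0.0183, 0.0237 and 0.0332. The most abundant leaf entry, miR528b, stood at 2.91e+05 CPM on day 0 and 3.08e+05 on day 8. miR399, which targets the PHO2 regulator of phosphate uptake, and miR827, which targets SPX-domain proteins, did not pass the test. Their log2 values were -0.84 for miR399e (edgeR adjusted p = 0.464), -1.07 for miR399i (0.259), -0.18 for miR827 (0.86) and -0.13 for miR827* (0.86).

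By the fixed lists, 10 of 22 entries of the phase-change list (miR156, miR172 and miR529) fell and 12 did not pass. The 10 were the miR156 entries above, which are not independent. Adjusted over the list alone, 10 fell and 1 rose. In the NF-Y list (miR169) 4 of 22 fell, and 1 of 14 fell in the copper and laccase list. No entry passed among 4 of the phosphate-starvation list, 24 of the auxin and TAS3 list, 52 of the growth-regulator list, 4 of the sulfate list and 5 of the silencing-machinery list. Of 52 star strands, 7 fell. No list as a whole passed limma's camera test, the nearest being phase change (adjusted p = 0.0586, and adjusted p = 0.843 with an estimated correlation). The copper list had a median log2 of 0.13 and a mean of -0.02, and its test pointed upward.

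The leaf decline rested on the scaling and on single libraries: 6 entries fell and 0 rose under median-ratio scaling, and 7 rose and 6 fell when scaled to listed reads, which moved the median log2 of all entries from 0.00 to 0.11. Those scalings left 2 of 17 miR156 entries falling, and in the latter 1 rose, while miR156a had edgeR adjusted p of 0.309 and 0.178. The 15 calls became 0 without leaf day 0 replicate 2, 8 without leaf day 0 replicate 1, and 7 (3 up, 4 down) without either root day 0 library, while miR156a had edgeR adjusted p between 0.277 and 0.305 with any root library left out. Leaving out leaf day 0 replicate 1 also ended the calls of miR156b* (0.202), miR169c* (0.112), miR169k* (0.153), miR169i* (0.253) and miR408b* (0.183), and without leaf day 0 replicate 2 miR169j* had edgeR adjusted p of 0.0537. Without leaf day 8 replicate 2, edgeR adjusted p was 0.0895 for miR156b*, 0.0663 for miR169c*, 0.0663 for miR169k* and 0.0961 for miR169i*, and without leaf day 8 replicate 1 it was 0.0774 for miR156b*. Without root day 0 replicate 1 or 2 it was 0.0648 or 0.0714 for miR169c*, 0.104 or 0.107 for miR169k*, and 0.121 or 0.116 for miR169i*.

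**Figure D1:**
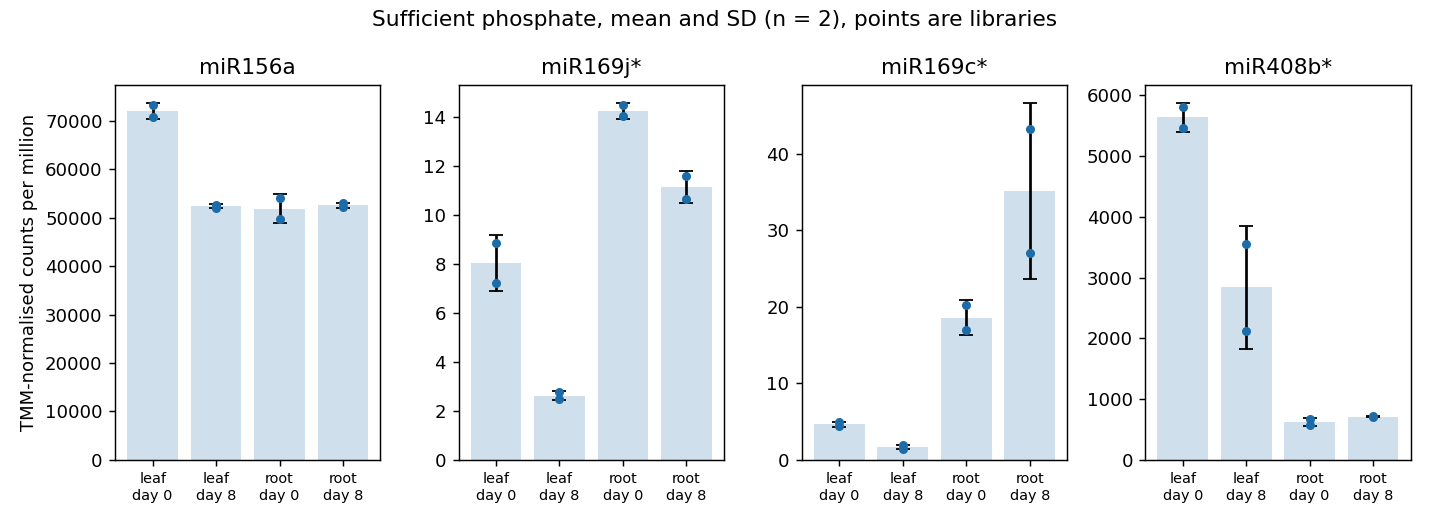
TMM-normalised CPM of miR156a, miR169j*, miR169c* and miR408b* in leaf and root on day 0 and day 8 at sufficient phosphate, with bars for the mean, error bars for the SD (n = 2) and points for single libraries. In leaf all 4 means are lower on day 8, while miR169c* in root stands at 18.6 on day 0 and 35.2 on day 8.

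In root the same 8 days gave 0 calls among 149 entries by edgeR's quasi-likelihood test, with 22 at an unadjusted p under 0.05. The 2 root day 8 libraries were placed by their titles, while another label gives day 0. This contrast, and the others that use root on day 8, rest on those titles. The entries nearest the threshold were miR169m*, miR1432, miR159c, miR172d* and miR172b*, all at an edgeR adjusted p of 0.0603. miR169m* had counts of 16 and 11 on day 0 and 50 and 32 on day 8, a log2 value of 1.74 (SE 0.37). miR1432 stood at 73.3 ± 2.62 CPM on day 0 and 158.97 ± 37.5 on day 8 (SD, n = 2). miR159c, of a family that targets MYB factors, had a log2 value of -1.79. Star strands of miR172, a family that targets AP2-like factors, had log2 values of -1.46 (miR172d*) and -1.45 (miR172b*). miR156a stood at 51886 ± 2936 and 52588 ± 494 CPM. Among phosphate entries, log2 was 0.05 for miR827 (edgeR adjusted p = 0.917), -0.63 for miR827* (0.339), -0.54 for miR399e (0.824) and -1.08 for miR399i (0.681).

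In root 2 lists passed the camera test with no member called. The NF-Y list lay higher on day 8 (median log2 0.50, camera adjusted p = 0.000464, but adjusted p = 0.577 with an estimated correlation, and fry 0.355), with 0 of 22 members called and 3 higher when adjusted over the list alone. The growth-regulator list, which holds families targeting MYB, NAC, HD-ZIP III, SCL, TCP and GRF factors, lay lower (median log2 -0.14, camera adjusted p = 0.00042, but adjusted p = 0.577 with an estimated correlation, and fry 0.574), with 0 of 52 members called. DESeq2 called 8 entries (4 up, 4 down), limma on log2 counts 0, median-ratio scaling 15 (8 up, 7 down) and scaling to listed reads 11 (6 up, 5 down). The count was 19 without either leaf day 8 library, 17 without root day 8 replicate 1, 9 without root day 8 replicate 2, 4 without root day 0 replicate 1 and 3 without root day 0 replicate 2.

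The comparison of organs at sufficient phosphate asked which miRNAs belong mainly to leaf or to root. Leaf held far more of the copper-associated families, which target laccases and other copper proteins. All 14 listed entries, which include star strands, were higher in leaf on both days, under each of the 3 scalings. miR528b was higher by a log2 of 3.30 on day 0 and 3.21 on day 8, miR398a, which targets copper/zinc superoxide dismutases, by 3.402 and 3.53, and miR397b by 4.03 and 3.45. The list's median log2 was 3.50 on day 0 (camera adjusted p = 7.81e-06, and adjusted p = 0.537 with an estimated correlation) and 3.49 on day 8 (camera adjusted p = 8.1e-06, and adjusted p = 0.552 with an estimated correlation). fry, which asks only whether a list's members lean one way, gave adjusted p of 0.00019 and 0.000264 for it.

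The phosphate entries were also higher in leaf at sufficient phosphate, 4 of 4 on both days. miR827 stood at 129 ± 13.8 CPM in leaf and 13.7 ± 1.14 in root on day 0 (SD, n = 2), a log2 of 3.23 (SE 0.27, edgeR adjusted p = 6.41e-07), and its log2 on day 8 was 3.00. The log2 of miR827* was 3.16 and 3.66. miR399e and miR399i were rare, with a log2 of 2.34 each on day 0 (edgeR adjusted p = 0.00153 and 0.00105). On day 8 miR399e had 13 counts in leaf and 3 in root, a ratio of 4.40 (counting interval 1.21 to 24.1), and miR399i had 11 and 2, a ratio of 5.59 (1.22 to 51.9). These rare entries depended on the setting: on day 8 scaling to listed reads left 2 of 4 passing. There miR399e had edgeR adjusted p of 0.0855 without leaf day 8 replicate 1 and 0.117 without root day 8 replicate 1, and miR399i had 0.0546 without leaf day 8 replicate 2 and 0.0628 without root day 8 replicate 1. On day 0 DESeq2 gave miR399e adjusted p = 0.0522 and miR399i 0.0542. The phosphate list had camera adjusted p of 0.110 and 0.118, and fry adjusted p of 0.00019 and 0.000264.

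Over all entries, 119 of 149 differed between leaf and root on day 0, 65 higher and 54 lower in leaf, and 113 differed on day 8, 58 higher and 55 lower. miR166j, of the family that targets HD-ZIP III factors, had the highest log2 on day 0, at 338 ± 5.32 CPM against 0.569 ± 0.69 in root on day 0 (log2 9.27, SE 0.56, edgeR adjusted p = 1.77e-07) and a log2 of 8.97 on day 8. Most of its family went the other way: of miR166 entries, 4 were higher and 13 lower in leaf on day 0, and 4 and 12 on day 8, with miR166a at -1.44 and -1.34. miR156j was higher in leaf, at 2631 ± 228 against 38.9 ± 3.82 CPM on day 0 (log2 6.08) and a log2 of 5.62 on day 8, and miR528a* by 5.16 and 5.47. miR171g, of a family that targets SCL factors, was lower in leaf by a log2 of -5.22 and -5.66. miR156b* had log2 values of -5.07 and -6.65.

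Several organ-restricted entries had counts at or near 0 in the other organ. miR167b* was at least 207-fold higher in root on day 0 and at least 227-fold on day 8, against a floor of 3 counts over the group. miR319b, of a family that targets TCP factors, was higher in root by a ratio of 277 on day 0 (counting interval 49.4 to 10974) and 355 on day 8 (63.2 to 14041). miR160a* was higher in root by 257 (45.8 to 10190) and 201 (55.3 to 1664). In leaf, miR396f* was higher by a ratio of 529.1 (94.4 to 20946) on day 0 and at least 131-fold on day 8, miR396e at least 34.01-fold on day 0 and by a ratio of 94.4 (16.5 to 3770) on day 8, and miR171e* at least 13.02-fold and 8.80-fold. Such intervals and floors cover counting error only.

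By list, the auxin and TAS3 entries split 9 higher and 11 lower in leaf on day 0 and 7 and 12 on day 8, with miR167b, which targets auxin response factors, at -2.53 and -2.64. Of the 5 silencing-machinery entries, 4 were lower in leaf, among them miR168a, which targets AGO1, at -0.76 and -0.87. The fifth, miR162, was higher at 1.43 and 1.30, though under scaling to listed reads 0 were higher. The NF-Y list had 4 higher and 8 lower in leaf on day 0 and 4 and 11 on day 8. Growth-regulator entries split 18 and 24, then 21 and 22, and star strands 19 and 24, then 17 and 25. Of 4 sulfate entries (miR395, which targets ATP sulfurylases), 1 was lower in leaf on day 0 and 0 differed on day 8. The phase-change list had 14 higher and 5 lower on day 0, but 6 and 6 under median-ratio scaling and 2 and 6 when scaled to listed reads, and 6 and 5 on day 8. Outside the lists, miR1432 was lower in leaf by -3.07 and -3.37. Scaling to listed reads turned the day 0 split to 41 higher and 69 lower, moving the median log2 of all entries from 0.36 to -0.41 on day 0 and from 0.26 to -0.34 on day 8, and median-ratio scaling moved it to 0.03 and -0.04.

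**Figure D2:**
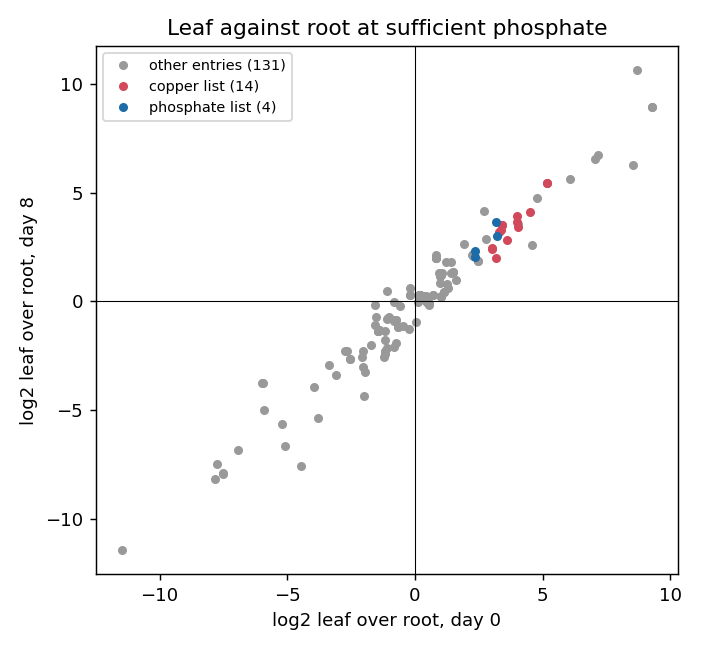
Log2 ratio of leaf over root at sufficient phosphate on day 0 (x axis) against day 8 (y axis) for each of the 149 tested entries, with 14 copper-list entries in red, 4 phosphate-list entries in blue and 131 others in grey. All red and blue points lie above 0 on both axes.

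Whether the stage change itself differed between the organs was tested as an interaction, leaf change minus root change. Of 149 entries, 9 differed. 6 of these were miR156 entries that share most of their reads, with miR156a at -0.48 (SE 0.12, edgeR adjusted p = 0.0441). miR169c* differed most, at -2.38 (SE 0.46, edgeR adjusted p = 0.0421), with leaf falling while root stood at 18.6 ± 2.24 CPM on day 0 and 35.2 ± 11.5 on day 8. miR169k* differed by -1.33 (SE 0.34, edgeR adjusted p = 0.0441). The single positive difference was miR167h*, at 1.47 (SE 0.37, edgeR adjusted p = 0.0441), with leaf at 927 ± 115 and 1405 ± 484 CPM and root at 142 ± 1.16 and 77.6 ± 7.70 (SD, n = 2). No phosphate entry differed, with log2 differences of -0.30 (miR399e), 0.00 (miR399i), -0.23 (miR827) and 0.50 (miR827*), and edgeR adjusted p from 0.746 to 0.993.

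For the interaction, the NF-Y list was lower in leaf relative to root (camera adjusted p = 0.0142, and adjusted p = 0.946 with an estimated correlation), with 2 of 22 members lower and 4 when adjusted over the list alone. The growth-regulator list was higher (camera adjusted p = 0.000735, and adjusted p = 0.946 with an estimated correlation), with 0 of 52 members called and a median log2 of 0.11. In the phase-change list 6 of 22 were lower, and adjusted over the list alone 10 were lower and 1 higher. Under median-ratio scaling 2 were higher and 2 lower, and under scaling to listed reads 3 and 2 against 1 and 8, with the median of all entries moving from -0.11 to 0.06 and no miR156 entry passing in either. The 9 calls became 0 without either leaf day 0 library, 19 and 20 without leaf day 8 replicate 1 and 2, and 5 without root day 0 replicate 1 or 2 or root day 8 replicate 2. With any root library left out, edgeR adjusted p was between 0.514 and 0.804 for miR156a and between 0.0576 and 0.255 for miR169k*. Without leaf day 0 replicate 1 or 2 it was 0.126 or 0.158 for miR169c* and 0.2 or 0.158 for miR167h*.

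The central question of the series was how miRNAs change at low phosphate. Over the 5 time points, 3 miR399 entries rose in each organ, and miR827* rose in root. Of 14 copper-associated entries, 3 fell in leaf and 4 in root. In leaf, miR399e rose by a slope of 1.65 log2 units per unit of log2(day + 1) (SE 0.29, limma adjusted p = 0.0123), with miR399i and miR399j, which share most of its reads, at 1.62 each. In root, miR399e rose by 1.49 (SE 0.29) and miR827* by 1.68 (SE 0.31), both at a limma adjusted p of 0.0195. miR827 had slopes of 1.11 in leaf (limma adjusted p = 0.142) and 1.59 in root (0.0643), and miR399b* had 2.15 (0.0601) and 1.82 (0.0914).

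The copper-associated entries that fell in leaf were miR408b* (slope -1.15, SE 0.27, limma adjusted p = 0.0364), miR398b* (-0.77, SE 0.14, 0.0146) and miR397b (-0.74, SE 0.17, 0.0364). In root they were miR528a (-1.22, SE 0.30, limma adjusted p = 0.0454), miR528b (-1.17, 0.0454), miR408b* (-1.17, 0.0396) and miR397b (-0.78, 0.0396). In all, 8 of 151 entries passed in leaf, 5 up and 3 down, with 34 at an unadjusted p under 0.05. In root 8 passed, 4 up and 4 down, with 27 unadjusted. The leaf total includes miR166m* (0.40) and miR172c* (0.31), rare entries reaching at most 2.32 and 1.71 RPM and named after their values were seen.

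As lists, the phosphate-starvation entries rose in leaf in 3 of 11 cases and in root in 4 of 11, and in 11 of 11 in each organ when adjusted over the list alone. Its camera adjusted p was 1.12e-08 in leaf and 1.3e-11 in root, with adjusted p = 0.281 and 0.164 with an estimated correlation, and fry gave 0.0859 and 0.049. In the copper list 3 of 14 fell in leaf and 4 of 14 in root, or 10 and 11 adjusted over the list alone. Its camera adjusted p was 6.52e-08 and 5.81e-15, with adjusted p = 0.281 and 0.101 with an estimated correlation, and fry gave 0.0859 and 0.049. The sulfate list lay higher in leaf (camera adjusted p = 0.0395, and adjusted p = 0.566 with an estimated correlation), with 0 of 5 members called and 1 adjusted over the list alone. Of the other lists in leaf, 1 of 22 phase-change and 1 of 48 growth-regulator entries rose, and 0 passed in the NF-Y, auxin and silencing lists in either organ. The phase-change list had a leaf median slope of -0.13, which became 0.12 when scaled to listed reads.

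The trend calls, and the copper calls among them, depended on scaling and on other settings. Over all entries, 5 rose and 1 fell in leaf under median-ratio scaling. Scaled to listed reads, 7 rose and 0 fell, and the median slope of all entries moved from 0.04 to 0.32. In root 4 rose and 0 fell under median-ratio scaling, with miR528b and miR408b* at a limma adjusted p of 0.0669, but 4 rose and 5 fell when scaled to listed reads. Entries that fell numbered 0 in leaf with leaf fitted alone and 1 with entries separate or near-identical entries merged, and 0 in root with entries separate, near-identical entries merged or a pseudocount of 10, and with that pseudocount 0 rose. Day 8 carried both trends, with 0 calls in leaf without leaf day 8, where miR399e had a slope of 1.26 (limma adjusted p = 0.225), and 0 in root without root day 8, where it had 1.03 (0.508). In leaf the count was 18 without leaf day 4, 4 without leaf day 1, and 5 without root day 0, 1 or 4. In root it was 18 without leaf day 4, 16 without leaf day 8, 5 without leaf day 1, 3 without root day 0, and 4 without root day 1 or 4. In leaf, limma adjusted p without leaf day 1, root day 0, root day 1 and root day 4 was 0.108, 0.0524, 0.0621 and 0.0674 for miR408b* and 0.103, 0.0679, 0.0646 and 0.0674 for miR397b. In root, without root day 0, root day 1 and root day 4 it was 0.0725, 0.0745 and 0.0544 for miR408b*, 0.0717, 0.0745 and 0.0544 for miR528b, and 0.102, 0.0682 and 0.0544 for miR397b. Without leaf day 0 or leaf day 1 miR528b in root had 0.0667 or 0.0754, without leaf day 1 miR408b* in root had 0.06, and without root day 0 miR827* had 0.0708. The edgeR test on reads recovered from the steps called 14 entries in leaf (12 up, 2 down) and 14 in root (11 up, 3 down). Blank cells entered that test as the reads equal to 0.5 RPM, which were set and not recovered.

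**Figure D3:**
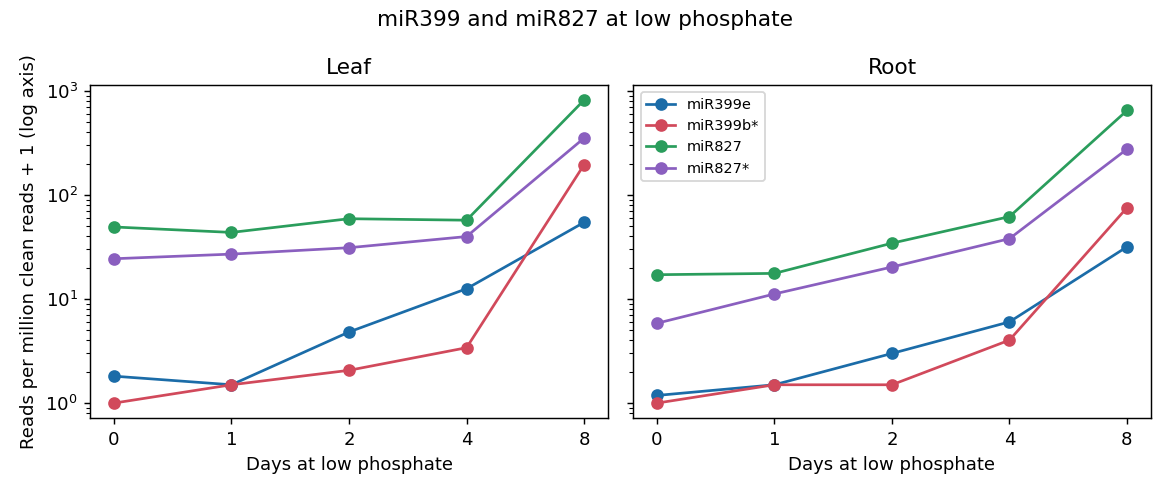
RPM plus 1 on a log axis for miR399e, miR399b*, miR827 and miR827* in leaf and root on days 0, 1, 2, 4 and 8 at low phosphate, drawn at equal spacing, with 1 library per point and blank cells drawn at 0.5. In both organs the highest point of every line is on day 8.

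No entry's slope differed between the organs by limma (0 of 151, with 9 at an unadjusted p under 0.05), and edgeR on recovered reads also called 0. The phosphate entries had slope differences from -0.60 for miR827* to 0.33 for miR399b*, with limma adjusted p of 0.912 and 0.985. The lowest p belonged to miR166m* (0.40), miR169a (-0.49), miR172c* (0.31), miR408 (0.75) and miR408b (0.76), all at a limma adjusted p of 0.576. Among the lists, sulfate had higher slopes in leaf (camera adjusted p = 0.000533, and adjusted p = 0.727 with an estimated correlation) and phase change had lower slopes in leaf (median -0.13, against 0.02 in root, camera adjusted p = 0.025, and adjusted p = 0.858 with an estimated correlation), with 0 members called in either. Scaling to listed reads moved the median slope difference of all entries from -0.01 to 0.29.

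Because LP time points had 1 library each, the size of change was described by a rule of size with no test: at least 2-fold on values plus 1, and at least 10 RPM in 1 of the 2 libraries. By day 8 the phosphate-starvation miRNAs stood far above day 0 in both organs. miR827 went from 48.3 to 816 RPM in leaf and from 16.1 to 648 in root, and miR827* from 23.4 to 351 and from 4.85 to 275. miR399b* went from 0 reads to 195 RPM in leaf, at least 876-fold, and from 0 to 74.5 in root, at least 405-fold. miR399e went from 0.815 to 53.6 in leaf, and in root from 3 reads to 30.8 RPM, a ratio of 167.1 (counting interval 56.8 to 813). Much of this lay after day 4, when miR827 stood at 56.3 in leaf and 61.0 in root and miR399e at 11.6 and 5.03. The median log2 fold of the 11 phosphate entries on day 8 was 4.05 in leaf and 4.69 in root, on values plus 1. Without the added 1, and with the 5 entries at 0 reads on day 0 in each organ set to their bounds, the medians were 62.0-fold and 74.3-fold. The log2 medians stood at the 99.99th and 100th percentile of 10000 random lists of the same size matched on mean expression. Such lists were drawn entry by entry, without regard to reads shared within a family, so the percentiles are not p-values.

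Most copper-associated miRNAs went the other way. miR528b went from 233652 RPM in leaf on day 0 to 59138 on day 4 and 82906 on day 8, and from 24046 to 1632 in root. miR408b* went from 6599 to 715 in leaf and from 471 to 35.9 in root, and miR397b from 333 to 82.1 and from 44.2 to 6.59. In leaf miR398b* went from 59.1 to 9.51 and miR397b* from 1930 to 464, and in root miR398a went from 12.1 to 1.75. Members did not all move alike: miR408 stood at 68.2, 180 and 102 in leaf on days 0, 4 and 8, but at 33.9 and 10.9 in root on days 0 and 8. The copper list's median log2 fold on day 8 was -1.73 in leaf and -1.70 in root, both below all of the random lists (percentile 0), with 11 and 9 of 14 entries lower by the size rule. In leaf this depended on scaling: scaled to listed reads the median was -0.81, and 2 entries in the whole leaf library were lower by the size rule. At sufficient phosphate over the same 8 days the median log2 change of this list was 0.13 in leaf and 0.18 in root. These values were normalised separately and set side by side with no test between them. In leaf at sufficient phosphate miR408b* itself fell (log2 -0.99, edgeR adjusted p = 0.0252), while 13 of the 14 entries did not pass.

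On the size rule, 38 entries differed from day 0 in leaf on day 8 (15 higher, 23 lower) and 30 in root (20 higher, 10 lower). Earlier days gave 16 (0 higher), 3 (0 lower) and 26 (15 higher) in leaf on days 1, 2 and 4, and 7 (3 higher), 3 (2 higher) and 13 (3 higher) in root. Of 78 entries measurable in both organs, 10 were higher in both on day 8 (13 in leaf, 12 in root). Independent lists of those sizes share 2. Another 7 were lower in both (19 in leaf, 9 in root), where independent lists share 2.19. Near-identical entries that share reads, such as miR399e, miR399i and miR399j, were counted separately, so the overlaps cannot be weighed against independent entries. The counts in leaf depended on scaling: on day 1 both other scalings gave 19 higher and 1 lower, and scaling to listed reads gave 38 higher and 6 lower on day 4 and 67 and 2 on day 8. Median-ratio scaling gave 17 and 18 in leaf and 16 and 13 in root on day 8, and 1 and 1 in root on day 2, while scaling to listed reads gave 2 and 5, then 1 and 1, in root on days 1 and 2. The authors' own double-star marks, from a test between pairs of single libraries, stood at 28, 12, 62 and 78 leaf entries on days 1, 2, 4 and 8 and at 17, 13, 34 and 65 root entries in the deposited table.

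Among other families on day 8, miR156a was lower in leaf by a log2 of -1.53, and miR156d, the third most abundant leaf entry, went from 108767 to 55238 RPM. miR172a went from 209 to 497 in leaf. These leaf values share the dependence on scaling given above. In root the most abundant entry, miR168a, stood at 111740 and 137338. List medians against random lists on day 8 stood at percentiles of 63.2 in leaf and 13.6 in root for sulfate, 1.75 and 0.16 for NF-Y, 1.04 and 28.6 for phase change, and 31.3 and 65.8 for auxin. They were 81.4 and 83.7 for growth regulators, 99.5 and 44.4 for silencing, and 11.5 and 22.99 for star strands.

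**Figure D4:**
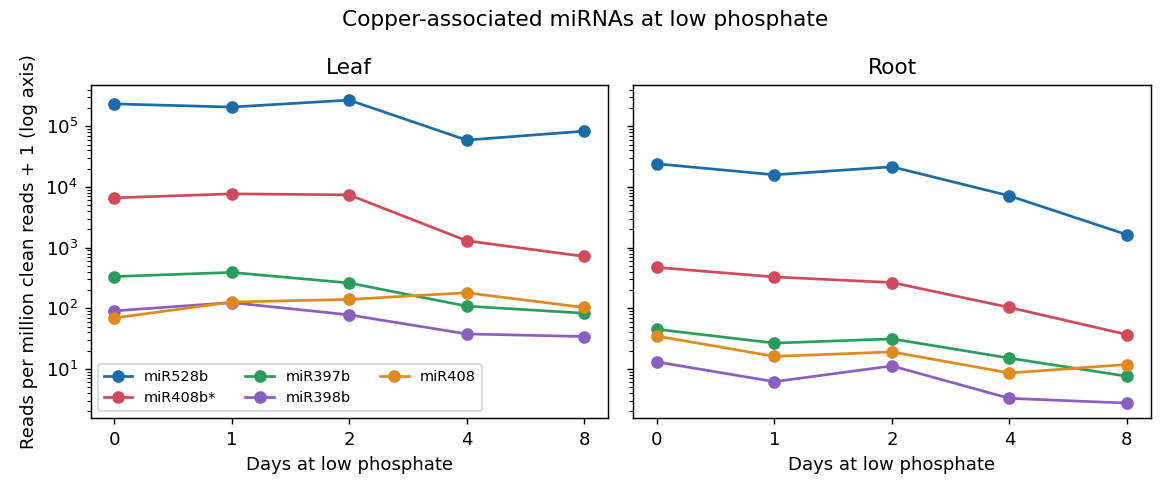
RPM plus 1 on a log axis for miR528b, miR408b*, miR397b, miR398b and miR408 in leaf and root on days 0, 1, 2, 4 and 8 at low phosphate, drawn at equal spacing, with 1 library per point. Day 8 lies under day 0 for every line except miR408 in leaf, which goes from 68.2 to 102.

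Leaf and root were also compared over all libraries of the LP series, 5 against 5, which asks whether the organ differences held across it. The 5 include day 0, before any days at low phosphate, and time points served in place of repeats. miR166j had the highest log2, at 212 to 456 RPM against 0.0935 to 1.23 in root (log2 7.66, SE 0.26, limma adjusted p = 2.45e-09). miR156j ranged from 905 to 2377 in leaf and from 80.4 to 99.1 in root (log2 4.04), and miR528b from 59138 to 269681 and from 1632 to 24046 (3.87). miR408b* (4.22), miR396f* (4.23), miR397b* (3.91) and miR398a (3.45) were higher in leaf as well. In root, miR167b ranged from 2629 to 3643 against 361 to 765 in leaf (-2.51). Also higher in root were miR167b* (-4.05), miR156b* (-3.86), miR319b (-3.35), miR166a* (-2.82), miR171h* (-2.36) and miR169c* (-2.06). All root values of miR396f*, and all leaf values of miR167b* and miR319b, were blank. The sizes of their log2 values therefore depend on the value set for blanks and are not measured folds. miR156b* was listed in only 2 leaf libraries, so its size depends partly on that value.

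The miR159 family went the other way at LP, with 0 of 5 entries higher and 5 lower in leaf (median log2 -0.90), against 4 of 6 higher on both days at SP (median log2 0.98 and 1.15). Scaled to listed reads, 0 were higher on either day at SP and 1 was lower at LP, and median-ratio scaling left 0 higher on day 0. miR156 entries had 5 higher and 9 lower at LP, against 12 and 3 on day 0 and 4 and 3 on day 8 at SP. The day 0 split was 4 and 3 under median-ratio scaling and 1 and 3 when scaled to listed reads. These families were named after their values were seen, and no test crosses the tables.

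In total 102 of 151 entries differed over the LP series, day 0 included, with 50 higher and 52 lower in leaf. The copper list had 13 of 14 higher in leaf (camera adjusted p = 8.21e-05, and adjusted p = 0.953 with an estimated correlation, with fry at 0.00145). In the sulfate list 4 of 5 were higher (camera adjusted p = 0.246, fry 0.0112). The auxin list had 7 higher and 11 lower of 24, silencing 1 and 3 of 4, phase change 8 and 10 of 22, growth regulators 14 and 22 of 48, NF-Y 3 and 5 of 21, and star strands 21 and 16 of 56. None of 11 phosphate entries passed, but with day as a factor miR827 (0.77, limma adjusted p = 0.0249) and miR399e (0.63, 0.0373) did. Scaling to listed reads moved the median log2 of all entries from 0.01 to 0.20.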

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

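The difference tests between organs given here were planned. At sufficient phosphate, the change from day 0 to day 8 differed between leaf and root for 9 miRNAs. The log2 difference, leaf minus root, was -0.48 for each of miR156a, miR156c, miR156e, miR156f, miR156g and miR156l, which share most of their reads and act as 1 signal. It was -2.38 for miR169c*, -1.33 for miR169k* and 1.47 for miR167h*. The 9 calls became 0 without either leaf day 0 library or without trend and robust settings, 4 under median-ratio scaling and 5 scaled to listed reads, with no miR156 entry passing under either scaling. As lists, NF-Y (miR169) members were lower in leaf relative to root, with a camera adjusted p of 0.0142 and adjusted p = 0.946 with an estimated correlation. Growth-regulator members were higher, with a camera adjusted p of 0.000735 and adjusted p = 0.946 with an estimated correlation.

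At low phosphate, the slope over days differed between leaf and root for 2 lists. Sulfate (miR395) members had higher slopes in leaf, with a camera adjusted p of 0.000533 and adjusted p = 0.727 with an estimated correlation. Phase-change members had lower slopes in leaf (median -0.13, against 0.02 in root), with a camera adjusted p of 0.025 and adjusted p = 0.858 with an estimated correlation. The median slope difference of the list, leaf minus root, was -0.23, and 0.10 when scaled to listed reads.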

How the results depend on the processing

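Chosen after seeing the data were limma on log2(count + 1), merging near-identical entries, blanks at 0 or 1, and edgeR on recovered reads. Over named entries and lists, 3116 values kept their direction and side, 285 became weaker, 138 stronger, 99 moved and 0 calls reversed, with no list test scaled to listed reads. Splits of call counts did turn: leaf day 1 went from 0 higher and 16 lower to 19 and 1 under both other scalings, and scaled to listed reads leaf day 8 went from 15 and 23 to 67 and 2 and the day 0 organ split from 65 and 54 to 41 and 69. The organ contrasts (119, 113 and 102 calls) stayed within 1.5 times under every setting tried. The stage, interaction and trend calls were less stable in number, and except where fewer or more entries or libraries entered, the cause was not tested.

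The 15 leaf stage calls became 6 under median-ratio scaling, 6 with no filter, 8 with DESeq2, 5 without trend and robust settings, 7 with only the compared groups and 6 with limma, and ranged from 0 to 18 when leaving out 1 library. For miR156a edgeR adjusted p was 0.0674 with near-identical entries merged and 0.378 with only the compared groups, and DESeq2 adjusted p was 0.512. The 0 root stage calls became 15 under median-ratio scaling, 11 scaled to listed reads, 7 with no filter, 10 with the stricter filter, 8 with DESeq2, 2 without trend and robust settings, 13 with entries separate and 14 with near-identical entries merged, and ranged from 0 to 19 when leaving out 1 library. The 9 interaction calls became 4 under median-ratio scaling, 5 scaled to listed reads, 5 with no filter, 4 with DESeq2, 0 without trend and robust settings and 3 with limma, with 0 to 20 when leaving out 1 library. A group left with 1 library is assumed to vary like the others.

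The 8 leaf trend calls became 13 with a pseudocount of 0.1, 5 with entries separate, 25 on a linear day scale, 3 with leaf fitted alone, 3 with near-identical entries merged, 14 with blanks at 1 and 14 with edgeR, and ranged from 0 to 18 when leaving out 1 library. The 8 root trend calls became 4 under median-ratio scaling, 18 and 0 with pseudocounts of 0.1 and 10, 14 with the stricter filter, 4 with entries separate, 24 on a linear day scale, 21 with root fitted alone, 2 with near-identical entries merged and 14 with edgeR, and ranged from 0 to 18 when leaving out 1 library. With an estimated correlation 0 lists passed in any contrast, against 2 in the root stage change, 1 in each sufficient-phosphate organ contrast, 2 in the interaction, 3 and 2 in the leaf and root trends, 2 in the slope difference and 1 in leaf against root at low phosphate. For lists in the leaf trend, median-ratio scaling gave 5 and separate entries 5, while separate entries gave 1 in the interaction and 2 in leaf against root at low phosphate.

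Of the size-rule counts, a pseudocount of 10 gave 1 and 17 in leaf on days 2 and 4 and 1 and 0 in root on days 1 and 2. Scaling to listed reads gave 44 and 69 in leaf on days 4 and 8. A 4-fold rule gave 0, 0, 10 and 14 in leaf and 0, 0, 5 and 18 in root on days 1, 2, 4 and 8. A minimum of 50 RPM gave 10 in leaf on day 4 and 0, 0, 5 and 10 in root. Separate entries gave 42 in leaf on day 4, and near-identical entries merged gave 6 in leaf on day 1.

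With the replicate number as a block, the stage calls were 13 in leaf and 0 in root, the organ contrasts 123 and 113, and the interaction 1. Same-numbered replicates deviated together with r of 0.01, 0.31, -0.17, -0.02, -0.12 and -0.14 over pairs of groups, so the numbers were not taken as pairing. Not run were pseudocounts for counts, DESeq2 for the low-phosphate signal, the compared groups alone for the interaction, which needs all 4 groups, and each organ alone for the slope difference, which needs both.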

Other observations

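The tests of age, scaling and capture given here were chosen after the result was seen, while the splits of libraries and orders of days were planned. Several miRNAs outside the phosphate and copper groups differed between single low-phosphate libraries, with no repeat to test a pair of days. None of those named here passed the trend test in either organ or the test of the slope difference. miR1432 stood at 58.4 and 20.4 RPM in leaf on days 0 and 8, and at 45.5 and 102 in root. With miR167j*, it was 1 of 2 entries that differed in opposite directions in the organs on day 8. miR395a, of the family that targets ATP sulfurylases, stood at 5.56 in leaf on day 0, 23.1 on day 4 and 9.18 on day 8, and between 1.12 and 2.86 in root. miR169k* stood at 1.11, 17.3 and 2.88 in leaf on days 0, 4 and 8, and at 2.70, 9.90 and 15.1 in root. These entries were named after their values were seen.

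The rise of miR399 and miR827 at low phosphate was set against plant age and scaling. Age alone would raise the same entries at sufficient phosphate. Only miR399e, miR399i, miR399j, miR827 and miR827* were tested in both tables, with miR399i and miR399j set against the same sufficient-phosphate entry. Over these, the smallest gap between a low-phosphate log2 fold and the upper 95% bound of its sufficient-phosphate change was 3.13. The lowest median log2 fold of the 11 entries over both organs and 3 scalings was 4.05, so scaling does not account for the rise. In root the age test also rests on the titles of the 2 SP day 8 libraries, which carry day 0 in another label. For entries not tested in both tables, age was not examined. The low-phosphate treatment may lie behind the rise of the entries that were, as a hypothesis. The tables were normalised separately and each low-phosphate time point is 1 library.

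The fall of the copper-associated list on day 8 at low phosphate was set against the same explanations, by organ. In root the list's lower quartile of SP changes lay at least 1.60 above its upper quartile of LP folds over all scalings tried. This argues against age only if the titles of the 2 SP root day 8 libraries hold, since another label gives them day 0. The root median was at most -1.70 under the deposited, median-ratio and outside-list scalings, which argues against scaling. In leaf the gap was 1.28 as deposited but 0.11 when scaled to listed reads, under the median difference between leaf day 8 replicates of 0.50, and the median was -1.73 as deposited but -0.95 when scaled to reads outside the list, so age and scaling stay open there. A response to low phosphate could explain the fall in root, as a hypothesis.

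miR160a, which targets auxin response factors, stood at 0.963 RPM in leaf on day 0 and 12.2 on day 8, with 27.3 on day 4, and in root at 1.23 on day 0, 1.54 on day 4 and 32.6 on day 8. Scaling would leave its ratio to miR160b* unchanged, but the log2 ratio went up by at least 4.61 in both organs. Low capture of miR160a in the early low-phosphate libraries fits the day 0 values. The ratio there was at most 0.18 at low phosphate, against 1.49 to 5.20 in the sufficient-phosphate libraries, and it was at least 3.93 on day 8. It reached 8.80 in leaf on day 4 and 5.43 in root on day 8, above the sufficient-phosphate range, which low capture alone does not explain. A technical loss in the early libraries may thus be the source of part of this rise, and a response to low phosphate was not separated from it.

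Chance groupings were examined by refitting. Of 100 splits of the 10 low-phosphate libraries into 5 and 5, 1 (the real one) called as many as the 102 entries of leaf against root. The highest other split called 2. Every other split mixes leaf with root libraries and so puts the organ difference into the error. Low counts there were fixed in advance, so the splits cannot decide whether chance plays a part. Of 100 orders of the days, 3 called as many as the 8 entries of the leaf trend, with 9 as the highest other, and 1 called as many as the 8 of the root trend, with 2 as the highest other. A chance order of days is therefore unlikely for the root trend, and less clearly so for the leaf trend, where another order called more. The orders cannot tell a trend from 1 deviating day 8 library, and day 8 carried both trends.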
